A study of Mus musculus with 3 samples.

How the data were processed

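The series holds 3 arrays of sorted splenic memory phenotype CD4 T cells from BALB/c mice, 1 from mice on a normal diet (ND) and 2 from mice on a high fat diet (HFD). Total RNA was extracted with Trizol and labelled with biotin by in vitro transcription, per the labels' protocols. The values are linear intensity per probe set as deposited by the authors, and GCOS, Affymetrix's array software, is the tool named per the submitters' processing notes. The algorithm, the background correction and the version are not given in the sources used here. From the values, the mean of each array after trimming 2% of probe sets at each end is 500.0 on every array, a scaling to a common mean that fixes each array's trimmed mean but leaves medians free (78.5, 70.0 and 67.6). Because of this scaling, a large change of bright transcripts on an array shifts all its other values the opposite way. Detection calls were not used here, so a dim value cannot be told from background. The number of arrays limits the precision.

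Of 45101 probe sets, 64 controls were set apart. Of the other 45037, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none, and only those with 1 symbol were named. Symbols were checked through Entrez identifiers against the RefSeq gene table of assembly GRCm38.p6, used for names only: 34741 probe sets matched, 0 symbols changed and 204 kept the annotation's symbol. The named probe sets covered 18193 genes. No coordinates are printed, since no genome build is named for the platform annotation.

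Values were kept on the deposited scale and transformed as log2(intensity + 17.65), the offset being the 25th percentile of all values. Genes entered where the mean over the 3 arrays was above 71.4, the median of all probe sets, and each gene was represented by its brightest probe set by mean intensity, leaving 10341 genes from 18953 probe sets. HFD was compared with ND by limma 3.58.1 (lmFit, then eBayes with a trend) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the genes tested and a call at an adjusted p under 0.05. With 1 ND array the residual has 1 degree of freedom per gene, from the HFD arrays alone, moderated with 11.69 prior degrees of freedom. A rule of size without a p-value counted genes at least 2-fold from ND in the same direction in both HFD arrays. Each array in turn was also taken as the lone one.

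A total of 28 gene lists (helper subsets, memory, lipid and energy metabolism, stress, and markers of other cell types) were fixed before the data were examined. The 27 lists with at least 5 measured members were tested by limma's camera with its preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists, beside the percentile of each list's median among 10000 random lists matched on mean expression in 20 bins. With the correlation estimated from the single residual degree of freedom, 0 of the 27 lists were called in camera. Of the unadjusted p-values 0 were under 0.05, the smallest being 0.138. Camera then also takes its p-values from 1 degree of freedom, so hardly any list could be called whatever its shift. Calls ended even where the estimated correlation lay below the preset 0.01, as for the cell cycle (-0.020) and glycolysis (-0.046) lists. Every list call thus rests on the preset setting, and the estimated one cannot decide on it.

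The genes named were chosen by a rule fixed at the same time. It took the 10 called genes higher and the 10 lower whose smaller difference to ND over both HFD arrays was largest, from each list up to 4 members with the largest such difference and up to 4 called members, and a fixed set of T cell and lipid genes, where measured. Other genes named below are said to have been chosen after their values were seen.

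The model was tested on simulated data for HFD against ND with the real means of 10341 genes, 200 of them changed. It recovered 80% of the changes of 1 and 96% of the changes of 2 on the log2 scale, called 4 unchanged genes, and camera called 0 lists where none was shifted. The simulated ND array varied like the HFD arrays, so the test does not bear on that assumption. Simulated genes varied independently of each other, so the 0 lists called do not bear on camera's preset correlation. Only 200 genes were changed, against 5132 called in the data, so recovery with so many changes was not tested. Alternatives covered the normalization, the offset, the filter, the merging of probe sets, the variance model, the thresholds, the settings of camera and leaving out each HFD array. Tables were handled with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and figures drawn with matplotlib 3.10.9.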

Results

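RNA abundance was measured on 3 Affymetrix mouse arrays, each hybridised with labelled total RNA from memory phenotype CD4 T cells, the antigen-experienced fraction of helper T cells, sorted from spleen to a purity above 99%. The BALB/c mice had received a normal diet (ND) or a high fat diet (HFD) with 60 kcal% fat for 10 weeks. The ND group held 1 array and the HFD group 2. Each array gave a linear intensity for 45037 probe sets besides controls, with a median of 78.5 on the ND array, 70.0 on HFD 1 and 67.6 on HFD 2. The number of arrays limits the precision. The labels do not say whether the HFD samples came from separate mice or pools, so p-values measure only the spread between these samples, which may be technical. Below, an HFD level is the mean intensity ± SD of its arrays (n = 2), and an ND level is the value of its single array, which has no error of its own. Fold changes are ratios on the log2(intensity + 17.65) scale, which understates the change of dim genes.

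The comparison asked which transcripts of splenic memory phenotype CD4 T cells differed between the diets. The ND array stood apart from both HFD arrays: the median absolute log2 difference per gene was 0.394 and 0.453 between ND and the HFD arrays and 0.126 between the HFD arrays. Of 10341 genes tested, 2117 rose and 3015 fell in HFD. Lists called higher covered oxidative phosphorylation, glycolysis, ribosomal proteins, protein folding, the cell cycle and cholesterol synthesis. Lists called lower covered Th2, Th17 and follicular helper T cells, memory and interferon response, and also myeloid and dendritic cell markers, among others. These calls rest on a preset correlation between genes, and with an estimated correlation 0 of 27 lists were called (adjusted p = 0.558 or 0.595 for each called list). That setting leaves 1 degree of freedom, so the adjusted p-values it gives here and below can hardly tell a shifted list from an unshifted one. Across genes, the Pearson correlation of the log2 values was 0.938 and 0.926 between ND and the HFD arrays and 0.991 between the HFD arrays (genes are not independent replicates).

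The calls came from limma's moderated test at an adjusted p under 0.05, and 1172 called genes, 715 higher and 457 lower, changed at least 2-fold. By a rule of size with no p-value, 620 genes were at least 2-fold higher and 269 at least 2-fold lower in both HFD arrays, against 55 genes at least 2-fold apart between the HFD arrays. The lower count depended on the settings, at 137 with the offset at the median of all values, 513 with no filter, 114 with the filter at the 75th percentile, and 439 or 632 with a single HFD array. With HFD 1 taken as the lone array, limma called 0 genes (27 at an unadjusted p under 0.05), and with HFD 2 it called 13 genes (229 at an unadjusted p under 0.05). These splits group ND with an HFD array, so the difference between them enters the residual. Few calls are then likely, and the counts do not measure the noise between HFD arrays. The median gene lay 0.15 lower in HFD on the log2 scale, so the medians of gene lists are given relative to all genes. The spread was estimated from the HFD arrays alone, and the lone ND array was assumed to vary like them. Diet cannot be told apart from any handling or array batch that the ND sample did not share. A strain difference against the labels also stays open, as set out below.

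**Figure D1:**
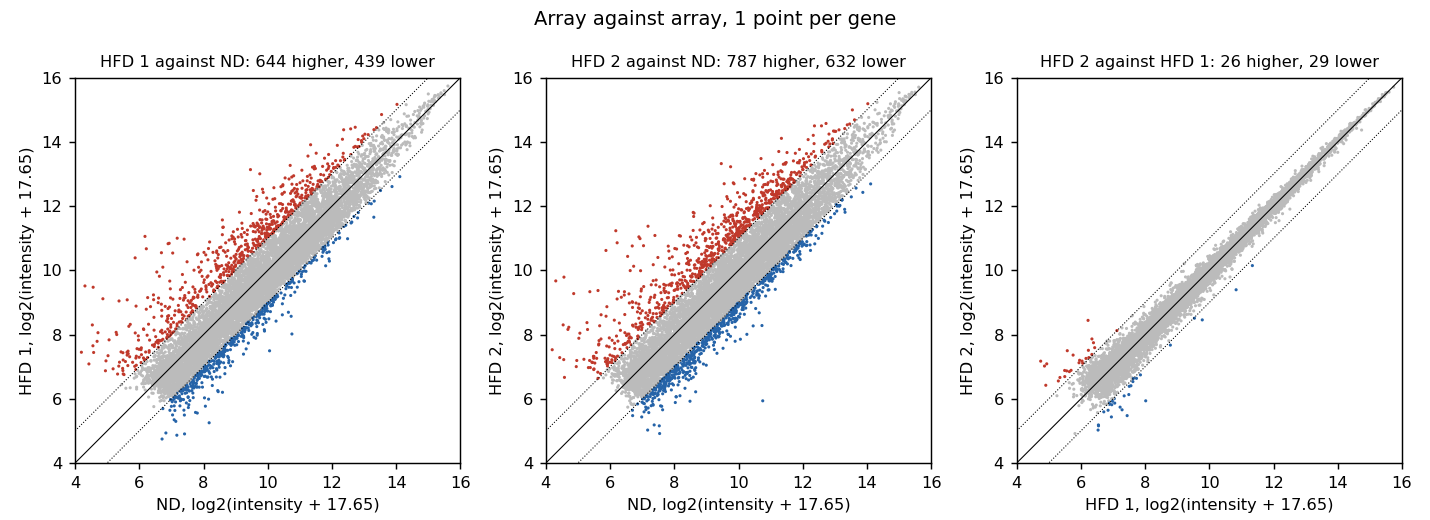
Log2(intensity + 17.65) of 10341 genes, 1 point per gene, for HFD 1 against ND, HFD 2 against ND, and HFD 2 against HFD 1. Red and blue points lie at least 2-fold above or below the diagonal (dotted lines mark 2-fold): 644 and 439 genes in the left panel, 787 and 632 in the middle, 26 and 29 between the HFD arrays.

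The genes with the largest increases in both HFD arrays spanned several functions. Crabp2, which encodes a retinoic acid binding protein, read 2.14 in ND and 755 ± 59.2 in HFD, 38.98-fold on the offset scale (log2 5.28 ± 0.22 SE, adjusted p = 4.3e-09). Bcat1, a branched-chain amino acid transaminase, rose 15.8-fold (104 to 1915 ± 138), and Mir155hg, the host transcript of a microRNA induced in activated lymphocytes, rose 16.1-fold (127 to 2332 ± 427). The others were Hacd1, AI506816, Ccnb1ip1, the B cell gene Ms4a1, the class II histocompatibility gene H2-Ea, Cnn3 and Lad1, at 15.6 to 33.6-fold. ND intensities of Crabp2, Hacd1 (5.96) and H2-Ea (11.5) lay under the offset of 17.65, so their folds depend on it. Folds are those of the brightest probe set, and other probe sets past the filter read less for Bcat1 (log2 1.13 to 2.68 against 3.98), Hacd1 (3.60 against 5.07), H2-Ea (2.99 against 4.33) and Cnn3 (2.71 to 3.07 against 4.04).

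Among the genes past the filter, the largest decreases were smaller. That filter takes the mean of 3 arrays, 2 of them HFD, so dim genes high in HFD pass it more readily than those high in ND. With no filter, the rule of size counted 778 genes higher and 513 lower. Cd160, an immunoglobulin-family receptor of T and NK cells, fell 4.94-fold (1679 to 327 ± 48.6, adjusted p = 3.7e-07), and Klf4, a transcription factor that restrains T cell proliferation, fell 3.89-fold (1581 to 394 ± 3.41, adjusted p = 5.4e-07). Their other probe sets fell less, at log2 -1.50 and -1.47 against -2.30 for Cd160 and -1.08 against -1.96 for Klf4. Slc40a1, the iron exporter ferroportin, fell 4.42-fold, and Bmp2, Cd209d, Serpina9, Qpct and Lratd1 fell 4.07 to 5.67-fold. Klk1 fell 5.22-fold on its brightest probe set, but 1 of its 3 other probe sets read higher in HFD (log2 1.39). G530011O06Rik fell 13.7-fold (1707 to 241 and 43.5 on the HFD arrays), a change whose adjusted p was 1.1e-04 and became 0.274 with a variance model robust to such spread.

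Oxidative phosphorylation and glycolysis genes were higher as lists in HFD, with single genes going either way. Of 73 measured oxidative phosphorylation genes, 53 rose and 4 fell (57 and 6 adjusted over the list alone), led by Ndufb6 of complex I (2.17-fold, 3267 to 7129 ± 257), the ATP synthase subunit Atp5md (2.09-fold) and Uqcrfs1 of complex III (2.01-fold). Uqcrq also rose, 2.05-fold, with its other probe set of opposite sign. The list median lay 0.52 above all genes, at percentile 99.99 of 10000 random lists matched on mean expression (camera adjusted p = 1.2e-10; adjusted p = 0.558 with an estimated correlation). Of 18 glycolysis genes, 11 rose and 3 fell (11 and 5 adjusted over the list alone), with Hk2, the inducible hexokinase, up 6.89-fold (274 to 1998 ± 181), the lactate transporter Slc16a1 up 4.74-fold, Pgam1 up 3.15-fold and Eno3 up 2.33-fold. This list lay 0.60 above all genes at percentile 99.63 (camera adjusted p = 0.0019; adjusted p = 0.558 with an estimated correlation).

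Cell cycle, protein and sterol genes were also higher. Of 39 cell cycle genes, 16 rose and 3 fell (16 and 3 adjusted over the list alone). The risers included the replication helicase genes Mcm3 (3.91-fold, 1379 to 5441 ± 163, its other probe sets log2 0.53 to 1.88 against 1.97), Mcm2 (3.81-fold) and Mcm5 (3.48-fold) and the cyclin gene Ccne1 (2.65-fold, its other probe set log2 0.65 against 1.41), all of which act at the start of DNA replication. The list median lay 0.49 above all genes at percentile 100 (camera adjusted p = 5.8e-04; adjusted p = 0.558 with an estimated correlation). Of 25 heat shock and unfolded protein response genes, 14 rose and 4 fell (16 and 5 adjusted over the list alone), among them the asparagine synthetase Asns (7.19-fold), the mitochondrial chaperones Hspd1 (4.21-fold) and Hspe1 (3.52-fold) and the glutathione-degrading enzyme Chac1 (2.78-fold). Its median lay 0.44 above all genes at percentile 98.13 (camera adjusted p = 0.0010; adjusted p = 0.558 with an estimated correlation).

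Of 46 cytosolic ribosomal protein genes, 23 rose and 2 fell (27 and 2 adjusted over the list alone), with the paralogs Rps27l up 2.66-fold and Rpl7l1 up 2.60-fold, Rps25 up 2.64-fold and Rps27 down 2.99-fold. The median lay 0.33 above all genes, but only at percentile 79.75 of lists matched on expression (camera adjusted p = 9.3e-06; adjusted p = 0.558 with an estimated correlation), and quantile normalization ended the call (median 0.12 above all genes, adjusted p = 0.0909). Of 22 cholesterol synthesis genes, 7 rose and 0 fell (7 and 0 adjusted over the list alone). Idi1, which isomerises isopentenyl diphosphate, rose 6.08-fold (790 to 4892 ± 183), and Sqle, Fdps and Cyp51 rose 3.01, 2.37 and 2.30-fold. This list lay 0.36 above all genes at percentile 98.73 (camera adjusted p = 0.0096; adjusted p = 0.558 with an estimated correlation).

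Camera called none of the lists of fatty acid synthesis, fatty acid oxidation, and lipid uptake, storage and efflux. Of 18 fatty acid synthesis genes, 6 rose and 5 fell (9 and 6 adjusted over the list alone; relative median 0.39, percentile 97.27, camera adjusted p = 0.246). Acaca, the acetyl-CoA carboxylase that commits carbon to fatty acids, rose 1.93-fold (log2 0.95 ± 0.17 SE, adjusted p = 6.2e-04; adjusted p = 0.0510 when its probe sets were averaged, the other reading log2 0.14), and Fasn, the fatty acid synthase, rose 2.63-fold (1153 to 3071 ± 185). The desaturase Scd2 fell 2.38-fold, Acss2 fell 1.89-fold and Srebf1, a lipogenic transcription factor, fell 1.29-fold (adjusted p = 0.0252; over 0.05 with no filter, without a variance trend, or with arrays centred). Scd1 read 46.0 in ND and 98.6 ± 8.15 in HFD (adjusted p = 0.0638), and was called higher under quantile normalization (adjusted p = 0.0480), with arrays centred (adjusted p = 0.0412) and without a variance trend (adjusted p = 0.0188). Of 23 fatty acid oxidation genes, 1 rose and 8 fell (1 and 8 adjusted over the list alone; relative median -0.03, percentile 40.72, camera adjusted p = 0.457), including Decr1 (1.75-fold) and Hadhb (1.41-fold). The carnitine transferase Cpt1a read 1654 in ND and 1573 ± 57.2 in HFD (log2 -0.07 ± 0.13, adjusted p = 0.663). Of 19 lipid uptake, storage and efflux genes, 1 rose and 9 fell (1 and 9 adjusted over the list alone; relative median -0.28, percentile 4.25, camera adjusted p = 0.196): the fatty acid binding protein Fabp5 rose 6.38-fold (1644 to 10620 ± 1110), while Apobr and the sterol exporter Abcg1 fell 2.41 and 1.89-fold.

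**Figure D2:**
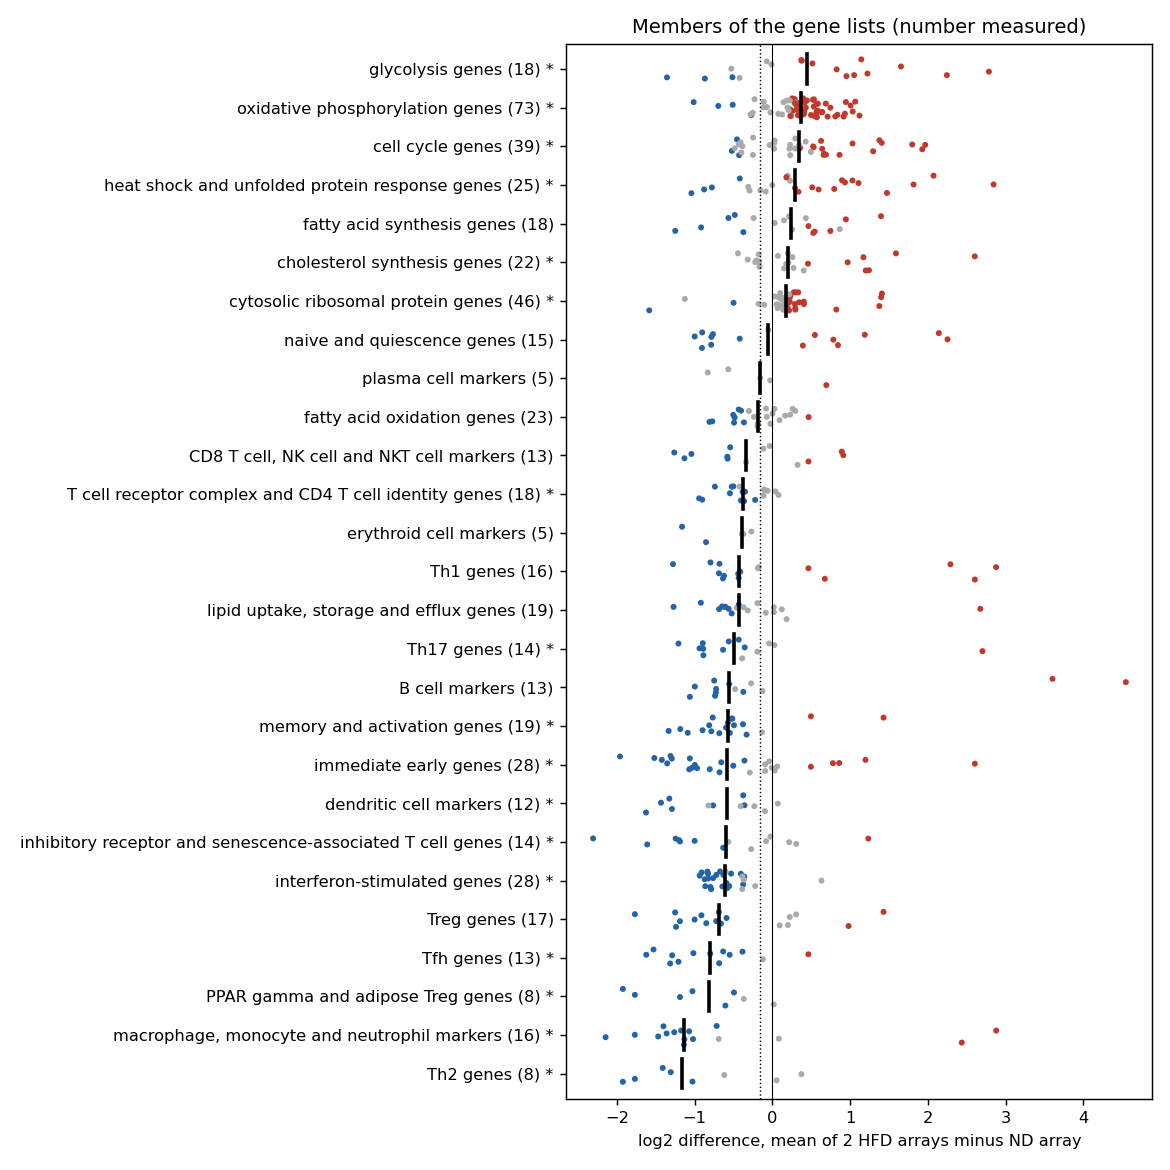
Log2 difference (mean of the 2 HFD arrays minus ND) of each measured member of 27 gene lists, with the number of members in brackets. Red, blue and grey points are genes called higher, called lower or not called, thick bars are list medians, the dotted line is the median of all genes (-0.15), and asterisks mark the 17 lists called by camera with the preset correlation. Glycolysis, oxidative phosphorylation and cell cycle genes have the highest medians and Th2 genes and myeloid markers the lowest.

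Genes of most helper T cell subsets were lower in HFD. Of 13 genes of follicular helper T cells, 11 fell and 1 rose (11 and 1 adjusted over the list alone): the lineage regulators Ascl2 and Bcl6 fell 3.08 and 2.49-fold, the follicle-homing receptor Cxcr5 2.44-fold (3289 to 1337 ± 42.1) and the cytokine Il21 2.31-fold (4212 to 1815 ± 41.3). The list median lay 0.65 below all genes at percentile 0 (relative median -0.65, camera adjusted p = 5.0e-04; adjusted p = 0.558 with an estimated correlation). Of 8 Th2 genes, 5 fell and 0 rose (5 and 0 adjusted over the list alone): Nfil3 (3.79-fold), Il10 (3.40-fold), Il17rb (2.66-fold), Il4 (2.47-fold) and the Th2 regulator Gata3 (2.04-fold, 2764 to 1350 ± 115). This list was called lower (relative median -1.01, percentile 0, camera adjusted p = 0.0258; adjusted p = 0.595 with an estimated correlation), and without the filter on low values the relative median was -0.41 and the call ended (adjusted p = 0.0773).

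Of 14 Th17 genes, 9 fell and 1 rose (10 and 1 adjusted over the list alone). Maf, Ahr and Ccr6 fell 1.85, 1.86 and 1.47-fold. Irf4, an activation-induced factor shared by several subsets, rose 6.51-fold (910 to 6048 ± 799; log2 2.70, against 1.08 on its other probe set). The cytokine Il17a read 76.8 in ND and 79.5 ± 18.8 in HFD (log2 0.03 ± 0.37, adjusted p = 0.959). The Th17 list was called lower (relative median -0.34, percentile 1.4, camera adjusted p = 0.0258; adjusted p = 0.558 with an estimated correlation), a call that ended when arrays were centred (relative median unchanged, adjusted p = 0.139) or the filter was stricter (relative median -0.50, adjusted p = 0.0850). Of 16 Th1 genes, 5 rose and 9 fell (5 and 9 adjusted over the list alone; camera adjusted p = 0.662): the chemokines Ccl3 and Ccl4 and the protease Gzmb rose 7.35, 6.08 and 4.89-fold. The cytokine Ifng fell 2.42-fold (5285 to 2209 ± 585) and its regulator Tbx21 fell 1.54-fold. The Th1 median was below and the mean above 0 (-0.42 and 0.16). Of 17 regulatory T cell genes, 2 rose and 11 fell (3 and 11 adjusted over the list alone), with Il2ra, the high-affinity interleukin receptor chain, up 2.69-fold, Izumo1r and Nt5e down 2.38 and 2.36-fold, and the lineage factor Foxp3 down by a log2 of 0.59 (622 to 409 ± 33.3). That list missed the threshold (camera adjusted p = 0.0513) but was called lower under quantile normalization (adjusted p = 0.0366) and with arrays centred (adjusted p = 0.0249; adjusted p = 0.558 with an estimated correlation). Calls for Ccr6, Foxp3 and Tbx21 ended under some settings, with no filter on low values (adjusted p = 0.0962 for Ccr6 and 0.0640 for Foxp3) or without a variance trend (adjusted p = 0.0713 for Ccr6 and 0.0510 for Tbx21).

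Most genes of the fixed memory and activation list fell as well. Of 19 measured, 16 fell and 2 rose (16 and 2 adjusted over the list alone). The member with the largest change, Il2ra, rose 2.69-fold (725 to 1985 ± 35.0). Those that fell included the tissue-homing receptor Cxcr6 (2.52-fold, 10180 to 4057 ± 691), the integrin Itga4 (2.13-fold), Cxcr4 (1.86-fold) and Cd44, the surface marker of memory phenotype cells (1.72-fold, 9761 to 5661 ± 54.6). The list was called lower (relative median -0.42, percentile 0.01, camera adjusted p = 8.0e-04, and adjusted p = 0.558 with an estimated correlation). Its fall does not show less activation, since genes induced by activation went both ways. Irf4 rose 6.51-fold and Il2, chosen after its values were seen, 13.6-fold, while 16 of 28 immediate early genes fell and 5 rose. Of 15 naive and quiescence genes, 7 rose and 7 fell (7 and 7 adjusted over the list alone; camera adjusted p = 0.457, direction up, against a median of -0.05 and a mean of 0.17): the lymph node homing receptor Ccr7 rose 4.77-fold (1396 to 6732 ± 571), Bach2 4.41-fold, with its 2 other probe sets at log2 -0.21 and 0.46 against 2.14, and Igfbp4 2.28-fold, while Foxo1 fell 1.87-fold. Of 18 T cell receptor and CD4 identity genes, 11 fell and 0 rose (11 and 0 adjusted over the list alone), among them Themis (1.92-fold), Cd4 (1.87-fold) and Cd3e (1.67-fold, 4167 to 2492 ± 93.1). That list was called lower (relative median -0.22, percentile 0.57, camera adjusted p = 0.0096; adjusted p = 0.595 with an estimated correlation). The Cd4 call ended with no filter (adjusted p = 0.0903) or without a variance trend (adjusted p = 0.0780).

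Of 14 inhibitory receptor and senescence-associated genes, 7 fell and 1 rose (7 and 1 adjusted over the list alone). Cd160, Sostdc1 and Csf1 fell 4.94, 3.05 and 2.30-fold, Klrg1 fell 2.28-fold, and the cell cycle inhibitor Cdkn1a rose 2.35-fold. Other probe sets fell less for Cd160 (log2 -1.50 and -1.47 against -2.30) and Csf1 (-0.43 against -1.20), and that of Cdkn1a rose less (0.67 against 1.23). The list was called lower (relative median -0.45, percentile 0.33, camera adjusted p = 0.0260; adjusted p = 0.558 with an estimated correlation), and averaging probe sets ended the call (adjusted p = 0.0511). Of 8 genes of PPAR gamma and adipose regulatory T cells, 6 fell and 0 rose (6 and 0 adjusted over the list alone; relative median -0.66, percentile 0.1, camera adjusted p = 0.0075; adjusted p = 0.558 with an estimated correlation). Its leading genes, Nfil3, Il10, Klrg1 and Gata3, also stand in other lists above, and Pparg itself was under the filter (30.3 in ND, 26.3 and 12.2 in HFD).

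Interferon-stimulated genes fell by small steps: 21 of 28 fell and 0 rose (21 and 1 adjusted over the list alone), with Isg20, Xaf1, Ifit2 and the antiviral enzyme Rsad2 down 1.91, 1.88, 1.83 and 1.82-fold. The list was called lower (relative median -0.46, percentile 0, camera adjusted p = 6.1e-05; adjusted p = 0.558 with an estimated correlation). Of 28 immediate early genes, which respond within minutes to stimulation, 16 fell and 5 rose (17 and 5 adjusted over the list alone). Jun fell 2.68-fold (4818 to 1805 ± 353), Dusp1, a phosphatase, fell 2.55-fold and Klf4 fell 3.89-fold, whereas Myc, a regulator of cell growth, rose 6.08-fold (777 to 4819 ± 268). This list was called lower (relative median -0.43, percentile 0, camera adjusted p = 0.0105; adjusted p = 0.558 with an estimated correlation).

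**Figure D3:**
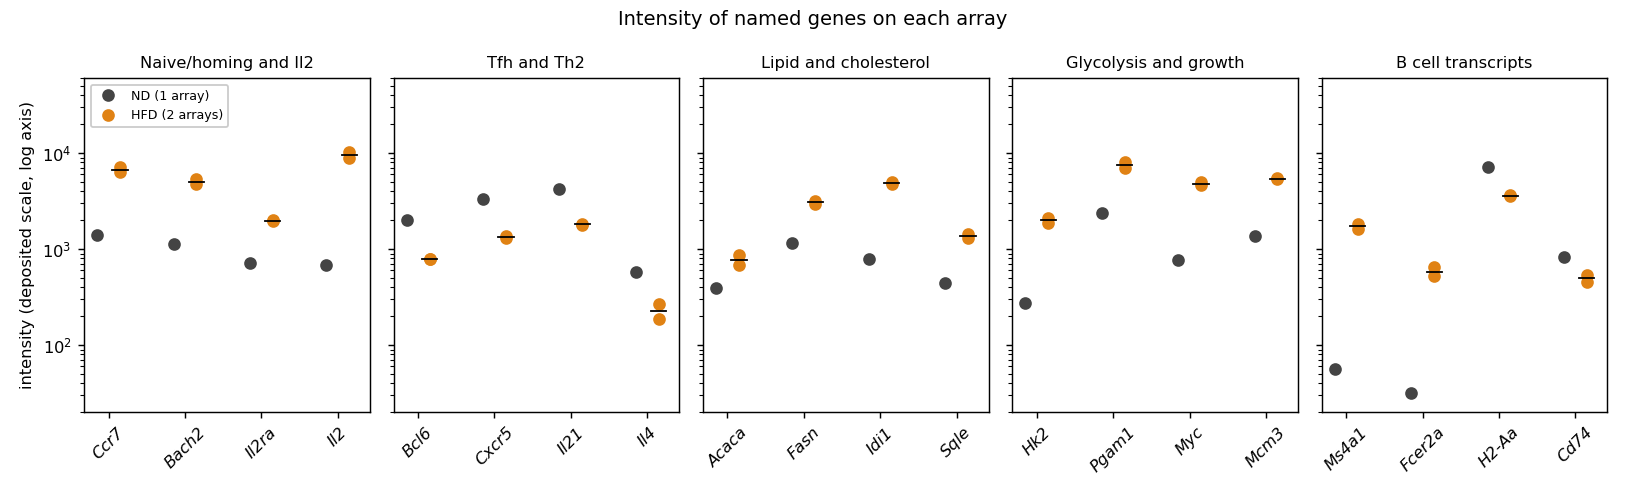
Intensity on the deposited scale (log axis) of 20 genes on each array: the ND array (dark point) and the 2 HFD arrays (orange points, with a bar at their mean). For each gene both HFD points lie on the same side of ND, above it for genes such as Ccr7, Hk2 and Myc and below it for Bcl6, Cxcr5, Il4, H2-Aa and Cd74; Il2 and Cd74 were chosen after their values were seen.

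Some markers of other splenic cells also differed between ND and HFD, although the labels give a sort purity above 99%. As lists, only the myeloid and dendritic markers were called. Of 16 macrophage, monocyte and neutrophil markers, 12 fell and 2 rose (13 and 2 adjusted over the list alone): Vcam1, Tyrobp and Fcer1g fell 3.41, 2.40 and 2.19-fold (Vcam1 log2 -1.77, but -0.17 on its other probe set), while the neutrophil genes S100a9 and S100a8 rose 7.36 and 5.41-fold from ND intensities of 5.85 and 40.9. The list was called lower in HFD, as were the Tfh, Th2, Th17 and memory lists on the same arrays (relative median -0.98, percentile 0, camera adjusted p = 0.0084; adjusted p = 0.558 with an estimated correlation). Of 12 dendritic cell markers, 7 fell and 0 rose (7 and 0 adjusted over the list alone), including Cd209a, Ccr9 and Siglech at 3.08, 2.70 and 2.50-fold, and the list was called lower (relative median -0.43, percentile 1.88, camera adjusted p = 0.0258; adjusted p = 0.558 with an estimated correlation) except under the stricter filter (adjusted p = 0.0649). Of 13 B cell markers, 2 rose and 8 fell (2 and 9 adjusted over the list alone; camera adjusted p = 0.181; called lower only on ranks, adjusted p = 0.0442): Ms4a1 rose 23.4-fold (56.8 to 1725 ± 159) and Fcer2a 12.1-fold (31.6 to 584 ± 85.3). The class II genes H2-Aa and H2-Ab1 fell, H2-Aa from 7207 to 3605 ± 83.0 and H2-Ab1 2.08-fold. The B cell median lay below and its mean above 0 (-0.55 and 0.10).

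Of 13 markers of CD8 T, NK and NKT cells, 3 rose and 6 fell (3 and 6 adjusted over the list alone; camera adjusted p = 0.435), with Gzma up 1.86-fold and Zbtb16 down 2.06-fold. Of 5 plasma cell markers, 1 rose and 0 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.861), namely Mzb1 at 1.62-fold (adjusted p = 0.0932 with no filter). Of 5 erythroid markers, 0 rose and 2 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.246), namely Car2 and Sptb at 1.81 and 2.24-fold (adjusted p = 0.0463 for Sptb, over 0.05 under several settings). Only 3 platelet markers were measured, too few to test, and 1 of them, Itgb3, fell 1.66-fold (0 higher and 1 lower adjusted over the list alone). Control probe sets spoke to RNA and hybridisation: the 3' over 5' ratio of beta-actin was 1.29 in ND and 1.27 and 1.34 in HFD. Hybridisation controls differed from ND by a median log2 of 0.06 and 0.05 over 18 probe sets, and poly-A spike-ins by -0.25 and -0.24 over 24 probe sets. Of these spike-in probe sets, 24 on HFD 1 and 20 on HFD 2 read lower than in ND. That shift was larger than the -0.15 of the median gene, and whether small falls of genes share it was not tested.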

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

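The tests of the ribosomal list's scaling, of other groupings of the arrays, of RNA degradation, of naive cells and of myeloid cells were chosen only after the results they bear on had been seen. The genes with the largest changes had been seen before any of the tests were set.

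Control probe sets for the transferrin receptor, outside the genes tested, were 5.6-fold higher in HFD (intensity 52.4 in ND, 356 and 393 in HFD). Among 3565 probe sets with no single gene name, 123 were at least 2-fold higher in both HFD arrays and 128 at least 2-fold lower, against 38 at least 2-fold apart between the HFD arrays.

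The first pattern is the size of the response, 5132 called genes with growth and metabolism lists higher in HFD. Scaling of the arrays as its whole source is argued against, since 83.3% of the lists called higher were still called under quantile normalization. With an estimated correlation, however, none of them is called by camera on the deposited scale (adjusted p = 0.558). Centring shifts all genes of an array alike and also altered the p-values, as set out below, so it decides nothing here. For the ribosomal list scaling stays a candidate explanation, because its median relative to all genes went from 0.33 to 0.12 (0.1171) under quantile normalization and its call ended. RNA degradation is argued against by beta-actin 3' over 5' ratios that differed by at most 1.037-fold between ND and an HFD array. Of the 3 ways to set 1 array against the others, 1 gave as many calls, the real one with 5132 against 13 for the next highest. The other ways grouped ND with an HFD array, which put the difference between them into the residual and made few calls likely. Also, 3 ways are too few to judge chance. Diet, handling and array batch cannot be told apart, and a strain difference, left open below, would bear on every call.

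The second pattern is the rise of Ms4a1, Fcer2a and H2-Ea in both HFD arrays. B cells in the HFD samples are argued against only in part: 15.38% of measured B cell markers rose, under the share set in advance, and 8 of the 13 fell. The fallen Cd74 and H2-Aa are class II genes, which are not restricted to B cells. Myeloid and dendritic marker lists fell on the same arrays, so the fall of these class II genes decides little. The labels give a sort purity above 99%, but H2-Aa read 7207 in ND and 3605 ± 83.0 in HFD, so the purity alone does not exclude B cells. A strain difference against the labels stays open: C57BL/6 mice lack H2-Ea expression and BALB/c mice have it, H2-Ea differed by 4.33 on the log2 scale from an ND value of 11.5, under the offset, and the gene chosen beforehand to decide it had no named probe set among the genes tested. A second H2-Ea probe set read 17.0 in ND and 256 and 260 in HFD. Other class II genes were higher in ND, such as H2-Aa (7207 against 3546 and 3664) and H2-Eb1 (2604 against 1566 and 1547). Of other genes looked at after the values were seen, Gbp2b rose 7.01-fold, like H2-Ea (207 in ND, 1415 and 1707 in HFD). Whether its rise comes from strain was not tested. Nnt, which part of the C57BL/6 lines lack in working form, was not called (limma adjusted p = 0.388), and Nnt alone decides nothing. The diet itself was not tested apart from these.

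The third pattern is the fall of memory, follicular and Th2 genes in both HFD arrays. Naive cells alone in the HFD samples are argued against, since of the 15 naive and quiescence genes 7 fell (46.67%) and 7 rose, Ccr7 the most. A share of naive cells stays open, and the labelled sort purity above 99% was not checked here. Of 16 myeloid markers 12 were higher in ND. A large myeloid share there as the sole source is argued against by the T cell identity list, since dilution in ND would raise its median. That median was -0.37 in HFD against ND and -0.22 relative to all genes (camera adjusted p = 0.595 with an estimated correlation). A small myeloid share would dilute the list too little to be seen, so the list cannot decide on it. A mixture of such shifts, or a change of the memory cells with diet, may still account for the pattern and was not tested. The labelled purity would limit such a mixture but does not exclude it, since the myeloid marker Tyrobp read 2217 in ND and 923 ± 178 in HFD.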

How the results depend on the processing

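All settings here were fixed together with the gene lists. The total of called genes stayed within 1.5 times of 5132 under both scalings, both offsets, both filters, averaged probe sets, both variance models and an adjusted p under 0.1. Of the 5132 calls, 4541 kept their sign and call under quantile normalization and 4786 with arrays centred, while 3480 did with no filter and 4197 with averaged probe sets (3 called the opposite way). Under quantile normalization and with arrays centred, the share of higher calls went from 41.25% to 46.12% and 47.18%. Genes called lower came to 1922 with no filter. Testing all probe sets gave 8218 calls (3455 higher, 4763 lower), since more units were tested, and asking also for 2-fold gave 1172 (715 higher, 457 lower).

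By the rule of size (889 genes, 620 higher and 269 lower), lower genes came to 137 with the offset at the median of all values, 513 with no filter and 114 with the filter at the 75th percentile (587 in all). The rule at 1.5-fold took 2857 genes (1316 higher, 1541 lower) and at 3-fold 243 (220 higher, 23 lower). Without HFD replicate 1 or 2 it took 1083 to 1419 genes (644 to 787 higher, 439 to 632 lower), fewer without replicate 2. Leaving out an HFD array leaves 1 array against 1 with no residual degrees of freedom, so calls and list tests have no value there. No paired analysis was possible because ND has a single sample with no number of its own.

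Of the lists, 17 were called (6 higher, 11 lower). With an estimated correlation the counts were 0 in all, 0 higher and 0 lower (0 at an unadjusted p under 0.05), where 1 degree of freedom made calls unlikely. Lists called lower were 6 under the filter at the 75th percentile. Centring reversed camera's direction for the uncalled Th1 and B cell lists while their relative medians stayed at -0.27 and -0.40. It also altered limma's p-values: the adjusted p of Il2 went from 6.6e-10 to 3.7e-195 while its log2 difference went from 3.77 to 3.84. P-values that small need far more prior degrees of freedom than the 11.69 of the main fit. Calls with arrays centred thus rest on another estimate of the spread. The uncalled Itga2b reversed to 0.0005 (log2) under quantile normalization. The cause of these changes was not tested. Dim genes are limited by signal over background.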

Other observations

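The gene families and genes here were chosen after the first results had been seen, the families' test before their own results.

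Protein synthesis and folding genes outside the fixed lists rose in HFD, with family medians of the same sign under quantile normalization. Of 29 genes of the small subunit processome and nucleolus, which build ribosomes, 27 rose (Nolc1 5.74-fold, Nop58 5.30-fold, Nhp2 5.20-fold), as did 18 of 19 cytosolic aminoacyl-tRNA synthetase genes (Iars 3.26-fold, Mars1 2.90-fold), 66 of 76 mitochondrial ribosomal protein genes (Mrps28 3.60-fold) and all 8 chaperonin genes (Cct6a 2.47-fold). Of 37 proteasome genes 31 rose and 3 fell, namely Psmb8, Psmb9 and Psmb10, the interferon-inducible immunoproteasome subunits. Of 45 genes with the Eif symbol of translation initiation factors 31 rose and 3 fell. Not all of them are such factors: Eif4ebp1, an inhibitor of initiation, rose 3.74-fold, and the kinases Eif2ak2 and Eif2ak3, which restrain initiation, fell beside Eif4e3. Of 14 RNA polymerase I and III genes 9 rose and 1 fell. Of 15 mitochondrial aminoacyl-tRNA synthetase genes 4 rose, and the family was not called (camera adjusted p = 0.10). In 7 of the 8 families at least 50% of members rose, consistent with a growth program that reaches beyond the fixed lists, a hypothesis found and tested on the same arrays. The other 7 had camera adjusted p of at most 4.0e-05, and all 13 families had an adjusted p of 0.366 to 0.398 with an estimated correlation.

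Of 5 further families, 4 were called lower with the preset correlation and none with an estimated one (adjusted p = 0.398 for the Gimap genes and 0.366 for the others). All 8 Gimap genes, GTPases of lymphocyte survival, fell (Gimap6 1.80-fold, camera adjusted p = 2.5e-04), as did 7 of 8 killer cell lectin-like receptor genes (Klrb1b 3.17-fold, adjusted p = 0.0038) and 11 of 14 sphingosine and chemokine receptor genes, of which Ccr7 alone rose (adjusted p = 0.0024; 9 fell under either other scaling). Of 11 cathepsin genes 8 fell and 2 rose (adjusted p = 0.0319), while of 26 autophagy genes 9 fell and 1 rose, a family that was not called (adjusted p = 0.0605).

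Single genes chosen after their values were seen include Il2, a growth factor of T cells made after receptor stimulation, which rose 13.6-fold (687 to 9610 ± 883), and Il3, which rose 7.68-fold. The serine hydroxymethyltransferase Shmt1, the spermidine synthase Srm and the amino acid transporter Slc7a5 rose 12.4, 10.3 and 7.72-fold. The transferrin receptor gene Tfrc rose 4.41-fold, like the control probe sets for it. The mitochondrial transhydrogenase Nnt read 1197 in ND and 1335 ± 138 in HFD (adjusted p = 0.388).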
